A study of Rattus norvegicus with 6 samples.

How the data were processed

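RNA sequencing counts from 6 rat libraries were compared, 3 labelled control siRNA and 3 labelled eIF3m siRNA. Group and replicate number were taken from the labels. The files hold 1 count per gene and library, which the authors deposited as whole numbers with no normalisation. Per the submitters' processing notes, the tools named are Trimmomatic 0.40, HISAT2 2.2.1, featureCounts, DESeq2 and limma, and the genome build is rn6; the notes give no order or role. The annotation and the counting settings for strand and for reads that map to several places are not given in the sources used here, so values of paralogues, pseudogene-rich families and overlapping genes are uncertain. Per the labels' protocols, libraries were made from 1.3 ug of total RNA with a SMARTER mRNA kit. The same protocol field also holds a text on dexamethasone, isobutylmethylxanthine and insulin feeding, which is a differentiation medium, and the labels do not say whether it was applied to these cells.

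The files list 31038 genes. In each file 27 symbols had been turned into calendar dates, a known effect of spreadsheet software, and they were left out because their genes cannot be told apart; they held 0.203% to 0.216% of each library's counts. At least 1 count was found for 22068 genes. The edgeR filter filterByExpr, with a minimum count of 10 and a minimum total of 15, kept 12724 genes. Of these symbols, 11071 matched a current rat symbol and 548 a synonym in a RefSeq table of assembly GRCr8, and 1105 matched neither. That table was used for names alone, and no coordinates are given because its assembly differs from the build of the files.

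Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, the quasi-likelihood F-test of eIF3m siRNA against control siRNA with no covariate, and Benjamini-Hochberg adjusted p under 0.05 (two-sided). Log2 fold changes are eIF3m over control and carry the standard error (SE) of the fit. Levels are CPM, the count relative to the TMM-scaled library total, given as mean ± SD of 3 libraries. A total of 3 counts, taken as the floor, was worth 0.285 to 1.32 CPM depending on the library, and floors cover counting error alone. The smallest library, eIF3m replicate 2, limits what can be seen at low levels.

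Gene lists were tested with camera of limma 3.58.1 on voom-weighted log2 values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 53 lists. The test compares a list with all other genes. Members past the threshold were counted among all genes tested and again adjusted over the list alone. Camera with an estimated correlation, and fry, which asks whether the members move one way without comparing them with other genes, were alternatives. The run with an estimated correlation differs in more than the correlation. For the endoplasmic reticulum list the estimate was -0.017, below the preset, yet the camera p rose from 2.74e-22 to 4.06e-04. A call lost in that run is thus no measure of how closely the members vary together. Of the listed members, 35 were not found in the files.

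The design, the 53 lists, the alternatives and the rule for the genes named were set before the data were examined, except where a choice is said to be made later. The rule takes Eif3m; the 8 highest and 8 lowest fold changes among genes past the threshold with a mean of at least 5 CPM in a group, no overlap between the groups' libraries and a symbol that is no placeholder; the 5 such genes with the lowest p; in each list the up to 4 called members with the lowest p; and Nos1, Nos2, Nos3, Cybb, Nox4, Sod2, Hmox1, Atf4, Nppa, Nppb, Myh6 and Myh7 whatever they show. Other genes named in a list, mostly those of a direction that 5 or fewer members took, were chosen after their values were seen. A few genes, among them some that the rule takes, are not reported here. The rule did not fix the scale on which groups must not overlap. TMM-scaled CPM was chosen after values had been seen, and on unscaled CPM Fbln2 and Col6a1 would replace Abi3bp and Cdca7 among the 8 highest, while the 8 lowest would be shared. The share of tested genes with separated groups was 48.5% on the first scale and 53.9% on the second.

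The edgeR and camera steps were tested on simulated counts for this comparison, over 12724 genes with 200 of them changed, in 10 draws for each of 2 kinds of spread. With gene-wise spread, 66.9% of the genes changed 1.5-fold and 80.7% of those changed 2-fold were recovered, and 8.40% of calls were genes left unchanged (5.88% to 11.4% per draw), which is above the nominal 5%. With spread drawn from the trend, 68.6% and 81.9% were recovered and 4.43% of calls were unchanged genes (2.60% to 6.28%). No changed gene was called in the wrong direction. A list shifted 1.3-fold was called in 10 of 10 draws of both kinds, and unshifted lists were called in 0.192% and 0% of tests. Genes were drawn independently of each other, so this share leaves out correlation between genes. It does not give the share of false calls among real lists. The gene shares do not carry over to the real calls either, since 4920 of the 12724 genes were called in the data.

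The alternatives set beforehand were relative log expression and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at 5 CPM in 3 libraries, leaving out the 20 most abundant genes, an adjusted p under 0.01, a replicate block and leaving out each library. After the data were seen, analysis with no scaling factors, with robust dispersion, with libraries thinned to the smallest total, and with no filter and robust dispersion together were added, as were a list of skeletal myoblast markers and a list of Y-linked genes. The tests of myocytes and fibroblasts as RNA sources were first run on genes picked after their levels had been seen. They were replaced by 4 genes named in the rule and by the whole fibroblast list, and both this choice and the limits for the verdicts were made with the levels known. No pair of libraries of a group was alike within sampling noise: the chi-square statistic per degree of freedom was lowest, at 1.83, for control replicates 1 and 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.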

Results

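The libraries came from rat cells that the labels describe as myocardial and call NRVM, a name they do not spell out. Their growth text gives the heart muscle of rat embryos as the origin. The cells had received a control siRNA (3 libraries) or an siRNA against eIF3m (3 libraries). eIF3m is a subunit of eukaryotic translation initiation factor 3, a complex that helps to bring the small ribosomal subunit to mRNA. Total counts were 7437285, 8237840 and 8603602 in control replicates 1, 2 and 3, and 10061575, 2156186 and 7901395 in eIF3m replicates 1, 2 and 3. The series title links eIF3m to nitrative injury of the ischaemic heart, and the comparison asks how the transcriptome differs when eIF3m is knocked down; the labels name no ischaemia for these libraries. They do not say that the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

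Eif3m was measured at 137, 136 and 141 CPM in control replicates 1, 2 and 3 and at 91.5, 83.9 and 87.3 CPM in eIF3m replicates 1, 2 and 3. The mean fell from 138 ± 2.58 to 87.6 ± 3.83 CPM (SD, n = 3 per group), a log2 fold change of -0.64 ± 0.05 SE or -35.9% (edgeR quasi-likelihood test, adjusted p = 1.41e-07). Transcripts of endoplasmic reticulum chaperones, lysosomal enzymes, integrins, calcium-handling proteins and muscle contractile proteins fell with the knockdown. A joint list of targets of the mechanosensitive YAP pathway and of serum response factor also fell. The targets of each factor were not tested apart. Transcripts of mitosis and DNA replication rose. With an estimated correlation the calls of the contractile and DNA replication lists were lost (adjusted p = 0.0548 and adjusted p = 0.0584). Among 12724 genes tested, 2220 rose and 2700 fell, and the median size of a change was 0.44 on the log2 scale. Changes of at least 2-fold were found for 520 genes, of which 333 rose and 187 fell.

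**Figure D1:**
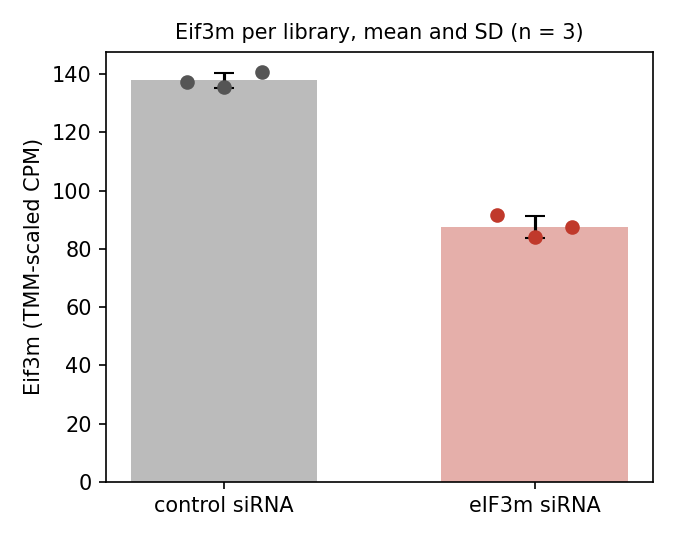
Eif3m level in TMM-scaled CPM (vertical axis) for control siRNA and eIF3m siRNA. Points are libraries, bars are means of 3 and error bars are SD; the eIF3m libraries lie between 83.9 and 91.5 CPM, all below the control libraries.

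The 8 lowest fold changes were those of Pln, Art3, Mybph, Lmod3, Ugt1a2, Itga8, Hspb7 and Camk2a. Pln, which encodes phospholamban, the inhibitor of the cardiac calcium pump, stood at 22.9, 24.9 and 27.2 CPM in controls and fell to 3.34 ± 1.35 CPM (log2 fold change -3.13 ± 0.19 SE, adjusted p = 5.48e-09). Art3, an ADP-ribosyltransferase family gene (-2.80 ± 0.20), Mybph, a myosin-binding protein (-2.57 ± 0.27), Lmod3, a thin-filament nucleator (-2.38 ± 0.21), Itga8, integrin alpha 8 (-2.29 ± 0.06), Hspb7, a small heat shock protein of muscle (-2.15 ± 0.07), and Camk2a, a calmodulin-dependent kinase (-2.12 ± 0.27), also fell. Ugt1a2 was at -2.38, but its gene family shares exons, so this value is uncertain. The lowest p-values belonged to Fn1, fibronectin (-0.62 ± 0.01 SE), Ctsb and Ctsd, lysosomal cathepsins B and D (-1.02 ± 0.02 and -1.13 ± 0.02), Ctgf, a matricellular YAP target (-1.05 ± 0.02), and Mfge8, a secreted glycoprotein that binds integrins (-1.13 ± 0.02).

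The 8 highest fold changes were those of Igfbp6 (5.54 ± 1.15 SE), Dcn (4.43 ± 1.03), Lum (3.21 ± 0.54), Mmrn2 (2.94 ± 0.67), Clec2g (2.80 ± 0.64), Stab1 (2.26 ± 0.51), Abi3bp (2.12 ± 0.26) and Cdca7 (2.10 ± 0.32), with adjusted p from 1.26e-05 to 0.00319. Dcn and Lum encode matrix proteoglycans of fibroblasts, and Mmrn2 and Stab1 are expressed by vascular endothelium. In eIF3m replicate 1 Dcn stood at 55.3 CPM, against 2.21 and 1.80 in eIF3m replicates 2 and 3 and 1.08 ± 0.167 in controls. Igfbp6 was at or under 3 counts in each control library, so the size of its change rests on a baseline near the floor. Without eIF3m replicate 1, Dcn (0.82 ± 0.51 SE), Mmrn2 (1.40 ± 0.65), Clec2g (1.11 ± 0.54) and Stab1 (1.08 ± 0.46) did not pass the test, while Igfbp6 (2.54 ± 0.87), Lum (2.28 ± 0.53), Abi3bp (1.99 ± 0.31) and Cdca7 (2.17 ± 0.37) did. Igfbp6 (1.77 and 1.20 CPM) and Lum (3.98 and 2.88) were low in eIF3m replicates 2 and 3. Those 2 genes, Dcn, Mmrn2, Clec2g and Stab1 all lay below 5 CPM there, so they met the rule's mean of 5 CPM only through eIF3m replicate 1. Lum stood at 0.849, 0.255 and 0.861 CPM in control replicates 1, 2 and 3, near or under the floor. With robust dispersion Igfbp6, Dcn, Mmrn2, Clec2g and Stab1 did not pass, and Dcn also missed the threshold with limma-voom. Without that library 1954 genes rose and 2449 fell in all, 4052 of the calls were shared in the same direction, and 269 rose and 211 fell at least 2-fold.

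Of 53 gene lists, 21 passed the camera test, 4 toward higher and 17 toward lower values, and 7 of them passed with an estimated correlation. For each called list the p with an estimated correlation was the highest of its 20 alternatives, except for the proteasome.

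Listed endoplasmic reticulum chaperones and unfolded protein response genes fell together: 0 rose and 25 fell of 26 tested (0 and 25 adjusted over the list alone), with a median log2 fold change of -0.55 (camera adjusted p = 1.45e-20; adjusted p = 0.0215 with an estimated correlation). The stress genes Ddit3 and Atf3, given below with the Atf4 targets, are not among these 26, and they rose. P4hb, a disulphide isomerase, fell from 2045 ± 36.1 to 1100 ± 31.0 CPM (-0.89 ± 0.02 SE). Hsp90b1 (-0.57 ± 0.02), the lectin chaperone Calr (-0.53 ± 0.02) and Hspa5, the luminal Hsp70 (-0.43 ± 0.02), also fell. Lysosome and autophagy genes followed, with 1 risen and 27 fallen of 41 (1 and 28 adjusted over the list alone), a median of -0.39 and adjusted p = 3.06e-12 (adjusted p = 0.0283 with an estimated correlation). Ctsb fell from 2647 ± 32.8 to 1301 ± 17.9 CPM, and Ctsd, the protective protein Ctsa and prosaposin, Psap, fell by 1.13, 1.08 and 0.77 on the log2 scale. The member that rose was Tfe3 (0.29 ± 0.05 SE), a transcription factor of lysosomal genes. In the list named for cytosolic heat shock proteins, 2 members rose and 12 fell of 23 (2 and 12 adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.0874 with an estimated correlation). Hspb7 fell as above, Hspb1 by 0.59, Hspa8 by 0.35 and Hsp90ab1 by 0.26 on the log2 scale. The members that rose were Hspe1 (0.18), whose protein is mitochondrial, and the co-chaperone Stip1 (0.19). Hspe1 did not pass with thinned libraries.

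Contractile and calcium-handling genes were lower. In the cardiomyocyte contractile apparatus 0 rose and 13 fell of 17 tested (1 and 14 adjusted over the list alone), with a median of -0.86 and adjusted p = 7.19e-07 (adjusted p = 0.0548 with an estimated correlation, the highest over alternatives that began at 5.79e-09). Tnnt2, cardiac troponin T, fell from 366 ± 8.85 to 152 ± 8.27 CPM (-1.27 ± 0.05 SE). Myom1, a protein of the M-band, fell by 1.07, Tnnc1, troponin C, by 0.97 and Pdlim5, a Z-disc protein, by 0.61 on the log2 scale. Cardiac calcium handling and ion channel genes counted 1 risen and 17 fallen of 28 (1 and 17 adjusted over the list alone), with adjusted p = 3.25e-06 (adjusted p = 0.0435 with an estimated correlation). Gja5, connexin 40, fell from 260 ± 2.31 to 73.5 ± 6.90 CPM (-1.80 ± 0.06 SE), Casq2, calsequestrin, by 1.22 and Atp2a2, the calcium pump that phospholamban inhibits, by 0.55; Gja1, connexin 43, rose (0.51 ± 0.06). Fetal and hypertrophy-associated genes counted 0 risen and 9 fallen of 17 (1 and 9 adjusted over the list alone; adjusted p = 0.00749, and adjusted p = 0.227 with an estimated correlation). Acta1, skeletal actin, fell from 22.7 ± 0.704 to 6.78 ± 0.828 CPM, Fhl1 by 0.59, Slmap by 0.32 and Fhl2 by 0.30 on the log2 scale. Of the 32 contractile members in the files, 20 had a control mean below 5 CPM. Of 21 skeletal myoblast markers, a list written after the data were seen, 14 were tested, and 2 rose and 9 fell (2 and 10 adjusted over the list alone). Myog, a transcription factor of muscle differentiation, fell (-1.84 ± 0.17 SE), as did Chrnd (-1.65), Myh3 (-0.86) and Chrnb1 (-0.63). Tmem8c also fell (-1.19), a call missed without control replicate 2 (-1.04, adjusted p = 0.0516). Eya4 rose (0.73), and Myod1 was at -0.09 ± 0.16 SE (adjusted p = 0.705). The atrial and ventricular myosins Myh6 (0.742 ± 0.105 CPM in controls) and Myh7 (0.0882 ± 0.0769) and the natriuretic peptides Nppa (1.09 ± 0.977) and Nppb (0.301 ± 0.292) lay near or under the floor and were not tested.

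Integrins and actin-linked adhesion genes counted 1 risen and 14 fallen of 24 (1 and 14 adjusted over the list alone; adjusted p = 8.30e-07, and adjusted p = 0.0435 with an estimated correlation). Itga7, the laminin receptor of muscle, fell from 1461 ± 6.67 to 637 ± 6.63 CPM (-1.20 ± 0.02 SE), Itgb1 by 0.95 and Itgb5 by 0.98 on the log2 scale, and Lims1, an adhesion adaptor, rose (0.24 ± 0.06). Targets of YAP and serum response factor counted 2 risen and 19 fallen of 26 (3 and 19 adjusted over the list alone; adjusted p = 6.82e-10, and adjusted p = 0.0435 with an estimated correlation). Ctgf fell from 2271 ± 17.4 to 1096 ± 24.5 CPM, Acta2, smooth muscle actin, by 0.52, Flna by 0.49 and Tpm2 by 1.02, whereas Tead1, the DNA-binding partner of YAP, rose (0.36 ± 0.05), as did Arhgap29 (0.49 ± 0.05). Smooth muscle and pericyte markers counted 2 risen and 10 fallen of 14 (2 and 10 adjusted over the list alone; adjusted p = 2.25e-04, and adjusted p = 0.254 with an estimated correlation). Pdgfrb fell by 0.96 and Tagln by 0.67 on the log2 scale, while Notch3 (1.39 ± 0.07) and Cspg4 (1.18 ± 0.26) rose.

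Extracellular matrix genes counted 10 risen and 25 fallen of 41 (10 and 25 adjusted over the list alone). Their median was -0.27 and their mean 0.11, and camera placed them lower (adjusted p = 2.25e-06; adjusted p = 0.0537 with an estimated correlation). Fn1 fell from 10100 ± 109 to 6576 ± 124 CPM, and Thbs1, Bgn and Sparc fell by 0.76, 0.63 and 0.89 on the log2 scale. Matrix genes that rose included Eln, elastin (3.42 ± 0.91 SE), which was at 0.04 without eIF3m replicate 1 and did not pass there. Without that library 5 rose and 26 fell. Its Hbb, beta globin, stood at 2133 CPM, against 72.9 and 17.4 in eIF3m replicates 2 and 3 and 20.5, 23.9 and 10.9 in controls. Cardiac fibroblast markers counted 8 risen and 4 fallen of 13 (8 and 4 adjusted over the list alone; adjusted p = 0.299), and 5 and 5 without that library. Thy1, Ddr2, Vim and Lox fell by 0.55, 0.42, 0.12 and 0.21 on the log2 scale, while Col1a1 (0.14 ± 0.01) and Tbx18 (0.46 ± 0.05) rose; Vim was at 0.03 with no scaling factors. Matrix proteases and inhibitors counted 5 risen and 8 fallen of 18 (5 and 8 adjusted over the list alone; adjusted p = 0.0483, and adjusted p = 0.227 with an estimated correlation). That call was also lost without control replicate 1 (adjusted p = 0.0581), eIF3m replicate 2 (0.0587) or eIF3m replicate 3 (0.0828). It was lost too with a replicate block (0.0551) and with the 20 most abundant genes left out (0.145), and its alternatives began at 1.46e-05. Timp2 fell by 0.83, Serpinh1 by 0.46 and Mmp14 by 0.99 on the log2 scale, while Mmp15 (1.41), Adamts2 (0.27), Adamts5 (0.72), Adamts9 (1.03) and Plat (0.16) rose; Adamts2 did not pass without eIF3m replicate 1 (0.17), nor Plat without control replicate 2 (0.13). Lox did not pass with upper-quartile scaling or no scaling factors, nor Eln with limma-voom or robust dispersion. Plat did not pass with no filter, nor Lox and Adamts2 with thinned libraries.

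**Figure D2:**
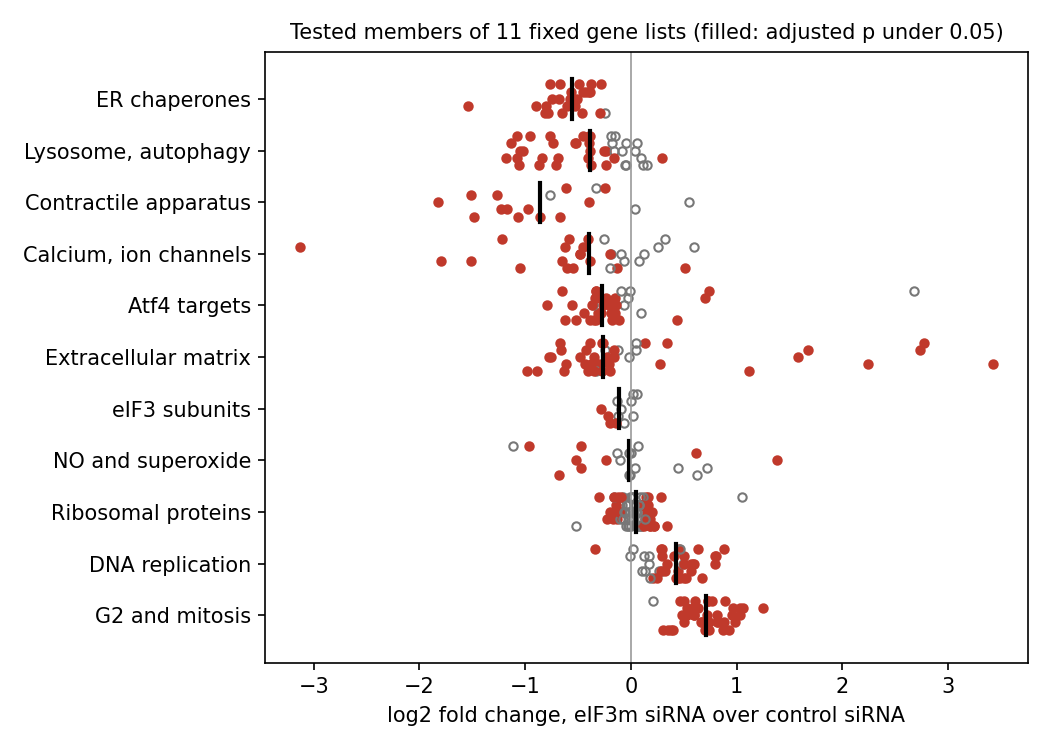
Log2 fold change, eIF3m siRNA over control siRNA (horizontal axis), of each tested member of 11 of the 53 lists (vertical axis, jittered), a choice made after the results were seen. Filled points have an adjusted p under 0.05 and black bars are medians, which run from -0.86 for the contractile apparatus to 0.71 for G2 and mitosis; the eIF3 subunits and nitric oxide lists turn positive with no scaling factors.

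Genes of mitosis rose, as did those of DNA replication, whose call was lost with an estimated correlation (adjusted p = 0.0584). The list of G1 cyclins and inhibitors did not pass (3 risen and 2 fallen of 13, adjusted p = 0.333). In the G2 and mitosis list 39 rose and 0 fell of 40 (39 and 0 adjusted over the list alone), with a median of 0.71 and adjusted p = 1.02e-19 (adjusted p = 0.0443 with an estimated correlation). Mki67, a nuclear antigen of dividing cells, rose from 156 ± 1.11 to 274 ± 7.49 CPM (0.81 ± 0.05 SE). Ncapd2, a condensin subunit, rose by 0.82, Cdk1, the mitotic kinase, by 0.60 and Top2a, topoisomerase II alpha, by 0.82 on the log2 scale. DNA replication genes counted 28 risen and 1 fallen of 41 (29 and 1 adjusted over the list alone; adjusted p = 8.46e-09, and adjusted p = 0.0584 with an estimated correlation). Prim1 (0.59 ± 0.07), Uhrf1 (0.50 ± 0.06), Rrm2 (0.60 ± 0.07) and Tk1 (0.79 ± 0.10) rose, and Fen1, the flap endonuclease, fell by 0.34. Immediate early and AP-1 genes counted 13 risen and 5 fallen of 30 (13 and 5 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.115 with an estimated correlation). Egr1 rose from 19.4 ± 3.91 to 60.7 ± 4.59 CPM, and Ier2, Dusp6 and Fos rose by 0.66, 0.65 and 0.73 on the log2 scale. The members that fell were Dusp1 (-0.43), Zfp36 (-0.42), Btg2 (-0.23), Ier5 (-0.15) and Klf6 (-0.11), and the last pair turned to 1e-04 and 0.04 with no scaling factors. Ier5 did not pass without control replicate 3 (-0.14), nor Klf6 without control replicates 1, 2 or 3 (-0.11, -0.095 and -0.11) or eIF3m replicate 1 (-0.07). Btg2, Ier5 and Klf6 did not pass with upper-quartile scaling, nor Btg2 with no scaling factors. Fen1, Btg2, Ier5 and Klf6 did not pass with thinned libraries.

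Of the eIF3 subunits other than Eif3m, 0 rose and 4 fell of 12 (0 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.178; adjusted p = 0.322 with an estimated correlation, in a range over alternatives of 0.00184 to 0.875); its median of -0.11 turned to 0.04 with no scaling factors. Eif3c fell from 631 ± 8.89 to 520 ± 11.3 CPM (-0.28 ± 0.03 SE), Eif3a was at -0.19 ± 0.03, Eif3l at -0.22 ± 0.05 and Eif3k at -0.14 ± 0.05, and the last 3 did not pass with no scaling factors. Eif3k did not pass when any of the 6 libraries was left out (from -0.13 without control replicate 1 or eIF3m replicate 1 to -0.15 without control replicate 2 or 3). Cytosolic ribosomal protein genes, a family with many pseudogenes, counted 20 risen and 12 fallen of 77 (20 and 12 adjusted over the list alone) with a median of 0.05 (adjusted p = 0.144; adjusted p = 0.774 with an estimated correlation, in a range of 2.59e-07 to 0.774). They passed toward higher values with upper-quartile scaling, a stricter filter, no scaling factors and thinned libraries, and without eIF3m replicate 3 (adjusted p = 0.00187). Rpl36 rose (0.34 ± 0.05), and Rpl10 (-0.23 ± 0.03), Rps27 (-0.30 ± 0.05) and Rpl3 (-0.14 ± 0.02) fell, Rpl3 turning to 0.0026 with no scaling factors. Targets of Atf4 in the integrated stress response counted 3 risen and 28 fallen of 38 (4 and 28 adjusted over the list alone), with a median of -0.27 (adjusted p = 6.17e-08; adjusted p = 0.0435 with an estimated correlation, the highest over alternatives that began at 5.91e-15). The amino acid transporter subunits Slc3a2 and Slc7a5 fell by 0.65 and 0.79 on the log2 scale, Vldlr by 0.62, the synthetase Eprs by 0.30 and Atf4 itself from 1125 ± 22.1 to 896 ± 27.6 CPM (-0.33 ± 0.03 SE). Ddit3 (0.74 ± 0.07), Atf3 (0.70 ± 0.11) and Ddit4 (0.43 ± 0.10), which are transcribed under several kinds of stress, rose, Ddit4 by 0.29 without eIF3m replicate 1. Eif3k did not pass with upper-quartile scaling, DESeq2, a replicate block, robust dispersion or thinned libraries.

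Initiation factors outside eIF3 counted 2 risen and 7 fallen of 30 (2 and 7 adjusted over the list alone; adjusted p = 0.233). Pabpc1, the poly(A)-binding protein, was at -0.26 ± 0.03 SE, Eif4g2 at -0.16 (-0.10 without eIF3m replicate 1) and Eif5b at -0.28, while Eif4h (0.16) and the cap-binding protein Eif4e (0.18) rose. Eif5b did not pass without control replicate 3 (-0.23) or eIF3m replicate 3 (-0.22), nor Eif4e without control replicate 1 (0.16) or 3 (0.16) or eIF3m replicate 2 (0.15) or 3 (0.16). Elongation and release factors counted 0 risen and 3 fallen of 10 (0 and 3 adjusted over the list alone; adjusted p = 0.201), which were Eef2 (-0.25 ± 0.01), Eef1a1 (-0.20 ± 0.01) and Etf1 (-0.24 ± 0.05). The proteasome list counted 1 risen and 11 fallen of 29 (1 and 12 adjusted over the list alone; adjusted p = 0.0416, and adjusted p = 0.296 with an estimated correlation). Its median of -0.08 turned to 0.07 with no scaling factors, and the call was lost without control replicate 1 (adjusted p = 0.0725), control replicate 2 (0.05004) or eIF3m replicate 3 (0.0933). It was also lost with upper-quartile scaling (0.216), DESeq2 (0.326), limma-voom (0.282), the stricter filter (0.129), no scaling factors (0.597) and thinned libraries (0.379). The list was called in 10 of 20 alternatives, in a range of 2.44e-04 to 0.597. The ATPase subunits Psmc1 and Psmc3 fell by 0.39 and 0.37 on the log2 scale, Psmd1 by 0.35 and Psmd2 by 0.24, and Psmd5, an assembly chaperone, rose (0.26 ± 0.06). COP9 signalosome and proteasome lid genes, which share domains with eIF3 subunits, counted 1 risen and 8 fallen of 17 (2 and 9 adjusted over the list alone; adjusted p = 0.129). Psmd8, Cops7a, Psmd3 and Psmd14 fell by 0.46, 0.35, 0.25 and 0.26, and Cops6 rose (0.16 ± 0.06), a call lost without control replicate 2 (0.13) or 3 (0.17) or eIF3m replicate 1 (0.11). Ribosome biogenesis genes counted 6 risen and 10 fallen of 42 (6 and 10 adjusted over the list alone; adjusted p = 0.5997), with Gnl3 (-0.37) and Utp20 (-0.47) lower and Ppan (0.33) and Nop58 (0.27) higher. Hosts of small nucleolar RNAs and other targets of nonsense-mediated decay counted 2 risen, Gas5 (0.30) and Upf1 (0.24), and 4 fallen, Gadd45b (-0.70), Gadd45a (-0.27), Atf4 and Smg9 (-0.24), of 13 (2 and 4 adjusted over the list alone; adjusted p = 0.253). Smg9 did not pass without control replicate 2 (-0.24) or 3 (-0.20) or eIF3m replicate 1 (-0.24), 2 (-0.21) or 3 (-0.26). Apart from the proteasome, the medians of these lists other than COP9 were between -0.09 and -0.02 and turned positive with no scaling factors. Smg9 did not pass with upper-quartile scaling or a replicate block, nor Eif5b, Eif4e, Cops6 and Smg9 with DESeq2. Cops6 did not pass with no filter, nor Eif4g2, Eif5b, Etf1, Psmd2, Psmd3, Psmd14 and Smg9 with no scaling factors. Eif5b, Eif4h, Etf1, Psmd14, Cops6, Utp20 and Smg9 did not pass with thinned libraries.

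Fatty acid oxidation and uptake counted 2 risen and 11 fallen of 28 (2 and 12 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.115 with an estimated correlation), and the call was lost with DESeq2. Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, fell from 113.9 ± 4.32 to 57.8 ± 0.630 CPM (-0.98 ± 0.05 SE). Angptl4, an inhibitor of lipoprotein lipase, fell by 2.06, Acadl by 0.61 and Hadha by 0.38 on the log2 scale, while Hadh (0.71 ± 0.17) and Ucp2 (0.55 ± 0.08) rose. Glycolysis counted 2 risen and 10 fallen of 22 (2 and 12 adjusted over the list alone; adjusted p = 0.0133, and adjusted p = 0.254 with an estimated correlation). Its call was lost with upper-quartile scaling and with no scaling factors, which turned the median of -0.14 to 0.0074. Slc2a4, the insulin-regulated glucose transporter, fell from 36.5 ± 3.53 to 13.3 ± 0.796 CPM (-1.44 ± 0.11 SE), Ldhb by 0.62, Pfkm by 0.52 and Aldoa by 0.36 on the log2 scale. Pfkfb3 (0.45 ± 0.05) and Eno3 (0.19 ± 0.06) rose, but Eno3 did not pass without control replicate 1 (0.17) or 2 (0.19) or eIF3m replicate 1 (0.18) or 3 (0.19). Cholesterol synthesis counted 2 risen and 10 fallen of 23 (3 and 13 adjusted over the list alone; adjusted p = 0.0141, and adjusted p = 0.316 with an estimated correlation), and the call was lost with DESeq2 and thinned libraries. Insig1, a regulator of sterol synthesis, fell by 0.98, Msmo1 by 0.60 and Cyp51 by 0.51 on the log2 scale, while Stard4 (0.74 ± 0.22) and Dhcr7 (0.44 ± 0.14) rose. Stard4 did not pass without control replicate 3 (0.66), nor Dhcr7 without control replicate 1 (0.38) or eIF3m replicate 3 (0.41). Eno3 and Dhcr7 did not pass with DESeq2 or thinned libraries, nor Eno3 with no filter or a replicate block.

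Nuclear complex I genes counted 3 risen and 4 fallen of 34 (2 and 1 adjusted over the list alone; adjusted p = 0.824), with Ndufb10 (0.43) and Ndufa5 (0.24) passing under each leave-out. Ndufa11 (0.21 ± 0.08) was lost without control replicate 1 (0.23) or 3 (0.15) or eIF3m replicate 1 (0.13), Ndufa8 (-0.28 ± 0.08) without control replicate 3 (-0.25) or eIF3m replicate 1 (-0.25) or 3 (-0.28), and Ndufs8 (-0.19 ± 0.06) without control replicate 1 (-0.15) or 3 (-0.19) or eIF3m replicate 3 (-0.15). Ndufc1 (-0.37 ± 0.12) was lost without control replicate 2 (-0.38) or 3 (-0.33) or eIF3m replicate 3 (-0.34), and Ndufb9 (-0.14 ± 0.05) without control replicate 1 (-0.12) or 3 (-0.14) or eIF3m replicate 2 (-0.11) or 3 (-0.14); Ndufb9 turned to 0.0034 with no scaling factors. Complexes II to V counted 1 risen and 12 fallen of 38 (0 and 12 adjusted over the list alone; adjusted p = 0.122), and the list passed toward lower values without eIF3m replicate 1 (adjusted p = 0.0267, in a range over alternatives of 0.00266 to 0.875). Cox6a1, Cox4i1, Atp5g1 and the muscle form Cox6a2 fell by 0.35, 0.33, 0.37 and 0.53 on the log2 scale; Atp5j (0.16 ± 0.06) was lost without control replicate 1 (0.16), 2 (0.15) or 3 (0.17) or eIF3m replicate 1 (0.11) or 2 (0.14). Mitochondrially encoded genes, whose share of counts was 6.30%, 6.33% and 6.58% in controls and 7.15%, 7.10% and 7.42% in the eIF3m libraries, counted 5 risen and 3 fallen of 13 (6 and 3 adjusted over the list alone; adjusted p = 0.210). CYTB (0.19 ± 0.02), ND5 (0.22 ± 0.02), ND1 (0.14 ± 0.02) and ND6 (0.19 ± 0.03) rose and COX2 (-0.22 ± 0.02) fell. COX3 was at 0.05 ± 0.02, ATP6 at -0.11 ± 0.02 and ND4 at -0.28 ± 0.10. COX3 did not pass without control replicate 1 (0.04) or 2 (0.04) or eIF3m replicate 1 (0.05), ND4 was lost without control replicate 1 (-0.29), 2 (-0.23) or 3 (-0.32) or eIF3m replicate 1 (-0.10) or 2 (-0.28) and passed at -0.45 without eIF3m replicate 3, and ATP6 turned to 0.04 with no scaling factors. The list passed toward higher values without control replicate 3 (adjusted p = 0.0366) or eIF3m replicate 1 (0.0206). It also passed with upper-quartile scaling (0.0186), no scaling factors (0.00129) and thinned libraries (0.0257), in a range over alternatives of 0.00129 to 0.720. Mitochondrial ribosomal protein genes counted 5 risen and 4 fallen of 54 (4 and 3 adjusted over the list alone; adjusted p = 0.595), with Mrps9 (0.44) and Mrps22 (0.47) higher and Mrps18b (-0.36) and Mrps12 (-0.37) lower. Mrps22 did not pass without eIF3m replicate 1 (0.35). Mrps26 (0.28) was lost without control replicate 1 (0.24) or 3 (0.27) or eIF3m replicate 1 (0.13), Mrps30 (0.23) without control replicate 2 (0.17) or eIF3m replicate 3 (0.19), and Mrps31 (0.34) without control replicate 1 (0.23) or eIF3m replicate 1 (0.31) or 3 (0.34). Mrps25 (-0.36) was lost without control replicate 2 (-0.27) or eIF3m replicate 1 (-0.28) or 3 (-0.33), and Mrpl33 (-0.29) without any library but control replicate 2 (from -0.33 without eIF3m replicate 3 to -0.21 without control replicate 3). Tricarboxylic acid cycle genes counted 3 risen and 5 fallen of 20 (3 and 5 adjusted over the list alone; adjusted p = 0.808). Fh, fumarate hydratase, rose (0.42 ± 0.05), as did Cs (0.15) and Idh3g (0.19), and Pc (-0.31), Pdha1 (-0.29), Dld (-0.19) and Idh2 (-0.20) fell. Cs ended without control replicate 1 (0.11) or 2 (0.16) or eIF3m replicate 2 (0.13) or 3 (0.16), Idh3g without control replicate 1 (0.19), 2 (0.22) or 3 (0.17) or eIF3m replicate 1 (0.14), and Idh2 without control replicate 1 (-0.16). Hypoxia response genes counted 2 risen and 4 fallen of 16 (2 and 4 adjusted over the list alone; adjusted p = 0.837), with a median of -0.0030, a mean of 0.012 and a test toward lower. Adm, adrenomedullin, rose (0.78 ± 0.06), and P4ha2 (-0.41), Vegfa (-0.16) and Ero1a (-0.29) fell. Mxi1 (0.25 ± 0.09) was lost without control replicate 2 (0.18) or 3 (0.25) or eIF3m replicate 1 (0.26) or 3 (0.24), and Ero1a without control replicate 3 (-0.21) or eIF3m replicate 3 (-0.22). Hif1a (-0.13 ± 0.05) was lost without any library but eIF3m replicate 3 (from -0.14 without control replicate 1 to -0.10 without eIF3m replicate 1) and turned to 0.01 with no scaling factors. The medians of the complex I, complexes II to V, cycle and hypoxia lists lay between -0.06 and -0.0030 and turned positive with upper-quartile scaling and no scaling factors. Hif1a did not pass with relative log expression scaling, nor Ndufa8, Ndufs8, Ndufc1, Ndufb9, ATP6, ND4, Mrpl33, Dld, Idh2, Vegfa, Ero1a and Hif1a with upper-quartile scaling. Ndufa11, Ndufa8, Ndufs8, Ndufc1, Ndufb9, Atp5j, COX3, ND4, Mrps30, Mrps31, Mrpl33, Cs, Idh3g, Ero1a, Mxi1 and Hif1a did not pass with DESeq2, nor Atp5j with limma-voom or the 20 most abundant genes left out. Atp5j, Cs and Idh3g did not pass with no filter, nor Ndufb9, Mrpl33 and Hif1a with the stricter filter. Ndufa11, Atp5j, Idh3g and Mxi1 did not pass with a replicate block, nor Ndufa8, Ndufs8, Ndufc1, ND4, Mrps12, Mrps25, Mrpl33, Pdha1, Dld, Idh2, Vegfa and Ero1a with no scaling factors. COX3, ND4 and Idh3g did not pass with robust dispersion, nor Ndufa11, Ndufs8, Ndufc1, Ndufb9, Atp5j, Mrps18b, Mrps12, Mrps30, Mrps31, Mrps25, Mrpl33, Idh3g, Pdha1, Dld, Idh2, Vegfa, Ero1a, Mxi1 and Hif1a with thinned libraries.

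Nitric oxide and superoxide genes did not pass as a list: 2 rose and 6 fell of 20 (2 and 6 adjusted over the list alone; adjusted p = 0.392, and adjusted p = 0.629 with an estimated correlation, in a range of 0.00342 to 0.629), and the median of -0.02 turned to 0.05 with upper-quartile scaling and 0.13 with no scaling factors. Duox1, a hydrogen peroxide-producing oxidase, fell from 145 ± 2.90 to 74.7 ± 3.00 CPM (-0.96 ± 0.05 SE), Xdh, xanthine dehydrogenase, by 0.47, Slc7a1, an arginine transporter, by 0.52 and Cav3, muscle caveolin, by 0.68 on the log2 scale. Arg2, a mitochondrial arginase (1.39 ± 0.28), and Ddah2, which degrades methylarginines (0.62 ± 0.11), rose. Nos1, Nos2, Nos3 and Cybb, the neuronal, inducible and endothelial nitric oxide synthases and a phagocyte oxidase subunit, were too low to be tested. Nos1 had 0 counts in each control library, 22 in eIF3m replicate 1 and 0 and 1 in replicates 2 and 3; Nos3 had 2, 4 and 2 in controls and 36, 2 and 2 in the eIF3m libraries; Cybb had 0 in controls and 17, 1 and 0. Nos2 had 1 count in control replicate 1 and 0 elsewhere. Most counts of Nos1, Nos3 and Cybb thus lay in eIF3m replicate 1, the library in which blood, vessel and leukocyte transcripts stood out. They cannot be read as a response to the siRNA. Nox4, a constitutively active oxidase, stood at 12.8 ± 1.95 and 12.8 ± 0.711 CPM (-0.007 ± 0.15 SE, adjusted p = 0.982).

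Antioxidant genes counted 10 risen and 13 fallen of 39 (11 and 15 adjusted over the list alone) and did not pass (adjusted p = 0.808). Their median was -0.04, their mean 0.03 and the test toward lower, and the median turned positive with upper-quartile scaling and no scaling factors. Txnip, an inhibitor of thioredoxin, rose from 112 ± 0.444 to 227 ± 26.3 CPM (1.04 ± 0.07 SE), Osgin1 rose (1.16 ± 0.12), and Gpx1, glutathione peroxidase 1, and Taldo1 fell by 0.78 and 0.43 on the log2 scale. Hmox1, haem oxygenase 1, was at -0.22 ± 0.03 (adjusted p = 1.35e-04), a call lost with no scaling factors. Sod2, mitochondrial superoxide dismutase, was at 0.16 ± 0.07 (adjusted p = 0.108) and passed with upper-quartile scaling, no scaling factors and without control replicate 1 (0.22). Interferon response genes counted 7 risen and 7 fallen of 34 (7 and 7 adjusted over the list alone; adjusted p = 0.543), and 5 and 7 without eIF3m replicate 1. Ifi27, Tap1 and Stat2 fell by 0.41, 0.36 and 0.33 on the log2 scale, and Eif2ak2, the double-stranded RNA kinase, rose (0.34 ± 0.05). NF-kappaB targets counted 4 risen and 7 fallen of 21 (4 and 7 adjusted over the list alone; adjusted p = 0.824), with a median of 0.05, a mean of 0.04 and a test toward lower. Tnfaip3, a feedback inhibitor of NF-kappaB, rose from 35.0 ± 2.84 to 79.7 ± 7.08 CPM (1.16 ± 0.08 SE), Lif rose (0.47 ± 0.09), and Icam1 and Nfkb2 fell by 0.50 and 0.44. Il6 (0.61 ± 0.18) and Vcam1 (0.61 ± 0.22) also rose; Il6 did not pass without control replicate 3 (0.49), nor Vcam1 without control replicate 1 (0.53), 2 (0.68) or 3 (0.61) or eIF3m replicate 1 (0.57) or 2 (0.54). Vcam1 did not pass with DESeq2 or no filter, nor Hmox1 with no scaling factors. Il6 and Vcam1 did not pass with thinned libraries.

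Blood, vessel and leukocyte transcripts stood out in eIF3m replicate 1. Erythroid markers summed to 6256 CPM there, against 240 and 54.5 in eIF3m replicates 2 and 3 and 75.6, 80.8 and 35.2 in controls; 3 rose and 0 fell of 5 (4 and 0 adjusted over the list alone; adjusted p = 0.272). Those were Hbb (5.36 ± 1.20), Hba1 (5.18 ± 1.18) and Hba2 (5.04 ± 1.18), near-identical alpha globin copies in the last pair; without that library Hbb (0.98 ± 0.37) passed and Hba1 (0.87 ± 0.41) and Hba2 (0.65 ± 0.44) did not. Without eIF3m replicate 3 the list passed (adjusted p = 0.0352, in a range over alternatives of 0.00548 to 0.691). Endothelial markers counted 3 risen and 2 fallen of 7 (3 and 2 adjusted over the list alone; adjusted p = 0.808), with a median of 0.47, a mean of 0.90 and a test toward lower. Flt1 and Egfl7 fell by 0.91 and 0.56, while Vwf (2.74 ± 0.72), Mmrn2 (2.94 ± 0.67) and Rasip1 (2.08 ± 0.47) rose; without eIF3m replicate 1 the last 3 stood at 0.17, 1.40 and 1.29 and did not pass. Macrophage and leukocyte markers counted 1 risen, Csf1r (1.18 ± 0.44, and 0.49 without eIF3m replicate 1, 1.13 without control replicate 1 and 0.88 without control replicate 3, none of which passed), and 1 fallen, Cd14 (-0.49 ± 0.10), of 4 (1 and 1 adjusted over the list alone; adjusted p = 0.824). Hbb, Hba1, Hba2 and Vwf did not pass with limma-voom or robust dispersion, nor Mmrn2 with robust dispersion. Csf1r did not pass with DESeq2.

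**Figure D3:**
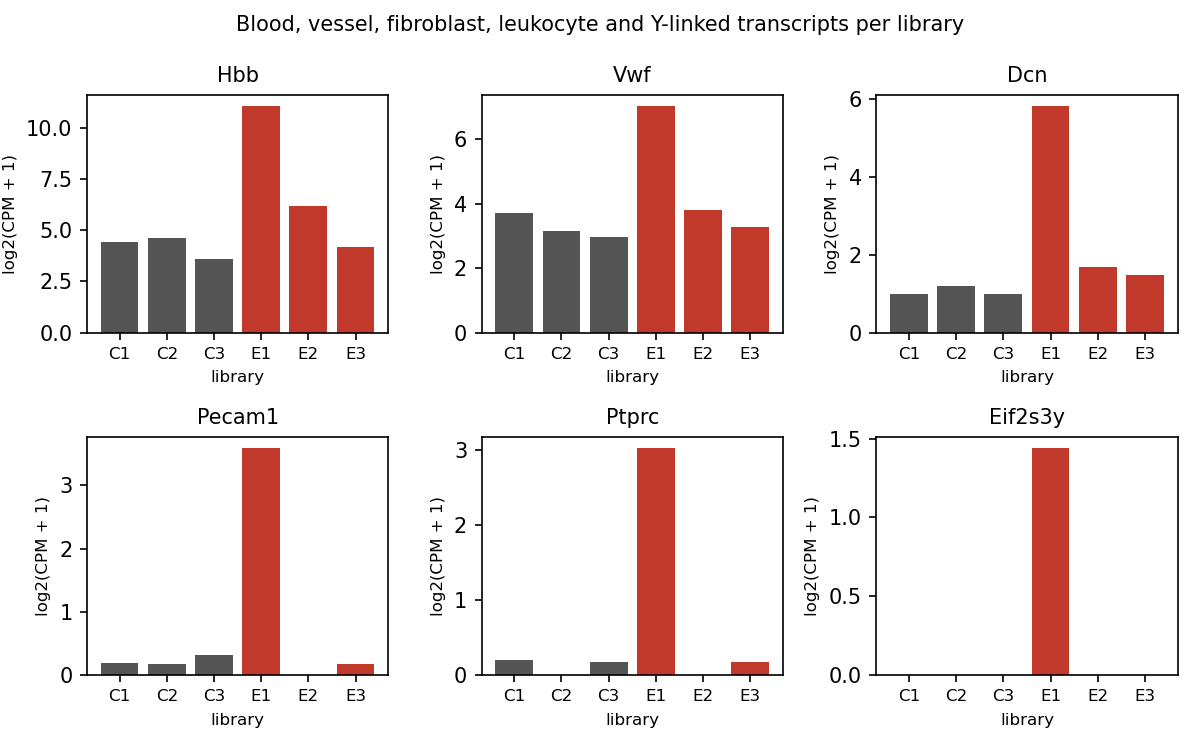
Level of 6 genes as log2(CPM + 1) (vertical axes) in control replicates C1 to C3 (grey) and eIF3m replicates E1 to E3 (red); bars are single libraries and the genes were chosen after the data were seen. eIF3m replicate 1 is highest in all 6 panels, with Hbb at 2133 CPM.

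Directions of small changes depend on the scaling. Of the changed genes, 45.1% rose with TMM, 58.6% with upper-quartile scaling and 71.2% with no scaling factors, which moved the median of all genes by 0.146.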

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

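The runs with no scaling factors, robust dispersion, thinned libraries and no filter with robust dispersion were chosen after the data were seen. Counting depth limits low genes, and the smallest library, eIF3m replicate 2, had 2156186 counts. Over the leave-outs of 1 library the number of changed genes ranged from 4090 to 4750, of higher genes from 1760 to 2128, of lower genes from 2330 to 2622 and of genes changed at least 2-fold from 464 to 512. Eif3m ranged from -0.67 to -0.62 there, was called under all 18 alternatives and was nearest 0 at -0.49 with no scaling factors. DESeq2 called 3767 genes and limma-voom 5081. Thinned libraries gave 3236 changed and 1411 higher genes. An adjusted p under 0.01 gave 1349 higher genes. With no scaling factors 4163 genes were higher and 1680 lower, since that run moves all genes up by 0.146. At least 2-fold changes numbered 972 without a filter, 830 without a filter and with robust dispersion, 260 with the stricter filter and 338 with thinned libraries; the cause was not tested. Without a filter the fitted prior degrees of freedom were infinite, so each gene's own replicate spread was not used, and those calls carry little weight.

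Of the 8 lists tied most closely to the design, the antioxidant, interferon and NF-kappaB lists stayed uncalled and the Atf4 target list stayed called under all 20 alternatives. The contractile list missed with an estimated correlation (0.0548). The eIF3 subunits passed without a filter (0.00733) and with fry (0.00184), and nitric oxide genes with fry (0.00342). Robust dispersion does not enter the camera step, so its list results repeat those with the same filter and are no added check. They are still counted among the 20 alternatives and the 896 values. Ribosomal proteins passed with upper-quartile scaling (0.00130), the stricter filter (0.03725), no scaling factors (2.59e-07) and thinned libraries (0.007455). The cause was not tested. Leave-outs gave adjusted p from 0.103 to 0.28 for eIF3 subunits, 0.00187 to 0.674 for ribosomal proteins, 0.271 to 0.528 for nitric oxide, 0.657 to 0.955 for antioxidant, 1.81e-07 to 1.52e-06 for contractile, 3.17e-08 to 1.48e-07 for Atf4 target, 0.509 to 0.619 for interferon and 0.678 to 0.948 for NF-kappaB genes. Of the other 45 lists 19 were called, 6 with an estimated correlation, 31 with fry, which asks another question, and 17 to 21 over the leave-outs. Their 896 values kept direction and side of the threshold in 818 cases, lost the call in 39, gained it in 39 and reversed in 0. For 297 named genes and 5288 values these numbers were 4870, 395, 12 and 11.

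With no scaling factors, which moves small negative values past 0, Eif3k turned to 0.0051, Rpl3 to 0.0026, Mdm2 to 0.0148, Ndufb9 to 0.0034, ATP6 to 0.0399, Hif1a to 0.0134, Ier5 to 1e-04, Klf6 to 0.0412, Fasn to 0.0144 and Vim to 0.0294. Eif5 ranged from -0.38 without eIF3m replicate 2, where its level was far above the rest, to 1.05 without eIF3m replicate 1. Same-numbered libraries did not deviate together over all tested genes, with correlations of deviations of 0.0304, -0.005 and 0.008. Counting noise of low genes enters these values, so they cannot exclude that the numbers pair the libraries. With a replicate block 4755 genes changed, 2123 higher and 2632 lower, 515 at least 2-fold, Eif3m was at -0.65 and 19 of the 45 lists were called; matrix proteases (adjusted p = 0.0551) were lost and erythroid markers (0.00548) gained.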

Other observations

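The tests of library size, of the odd library and of cell identity were chosen after the results they measure were seen, and the counts over splits of the samples were set beforehand. Splicing factor genes counted 20 risen and 7 fallen of 40 (21 and 8 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0303, and adjusted p = 0.316 with an estimated correlation). The call was also lost without eIF3m replicate 3 (adjusted p = 0.0553), with limma-voom (0.0811) and with no filter (0.0783), in a range over alternatives of 3.62e-04 to 0.316. Srsf7 rose from 563 ± 1.85 to 720.3 ± 27.9 CPM (0.36 ± 0.03 SE) and Srsf10 by 0.44 on the log2 scale, while Ptbp1 (-0.26) and Sf3b2 (-0.34) fell. Of the replication-dependent histones, Hist1h1c rose from 53.5 ± 2.13 to 123.02 ± 1.66 CPM (1.21 ± 0.05 SE), 1 of 4 tested (1 and 0 adjusted over the list alone). The list did not pass (camera adjusted p = 0.0893). It passed without eIF3m replicate 3 (0.0404) and with DESeq2 (0.0294), limma-voom (0.0243), no filter (0.0399) and fry (8.76e-04). The range over alternatives was 8.76e-04 to 0.284. G1 cyclins and inhibitors counted 3 risen, Cdk2 (0.44), Cdkn2a (0.52) and Cdkn2b (0.32), and 2 fallen, Ccnd1 (-0.20) and Rb1 (-0.35), of 13 (3 and 2 adjusted over the list alone; adjusted p = 0.333). Cdkn2b was lost without control replicate 2 (0.37) or 3 (0.22) or eIF3m replicate 2 (0.35) or 3 (0.20), and Rb1 without any library but control replicate 2 (from -0.38 without eIF3m replicate 1 to -0.32 without eIF3m replicate 2 or control replicate 3). Targets of p53 counted 5 risen, Fas (0.36), Cdkn1a (0.26), Ephx1 (0.23), Sesn1 (0.65) and Bbc3 (0.26), and 3 fallen, Gadd45a (-0.27), Btg2 (-0.23) and Mdm2 (-0.13), of 25 (7 and 4 adjusted over the list alone; adjusted p = 0.429). Ephx1 was lost without control replicate 1 (0.20) or eIF3m replicate 1 (0.17), Sesn1 without control replicate 3 (0.52), Bbc3 without control replicate 1 (0.28) or 3 (0.21) or eIF3m replicate 1 (0.21), and Mdm2 without control replicate 2 (-0.12) or 3 (-0.12) or eIF3m replicate 2 (-0.12), turning to 0.01 with no scaling factors. Apoptosis regulators counted 5 risen and 6 fallen of 30 (4 and 5 adjusted over the list alone; adjusted p = 0.888). Birc5, a mitotic inhibitor of apoptosis, rose from 18.9 ± 1.92 to 39.8 ± 4.07 CPM (1.06 ± 0.11 SE), Bcl2l11 (0.61) and Diablo (0.20) rose, and the survival genes Bcl2l1 (-0.62) and Mcl1 (-0.34) fell; Birc2 (0.22) was lost without control replicate 2 (0.18) or 3 (0.24) or eIF3m replicate 2 (0.19) or 3 (0.21), and Ripk3 (0.16) without any library but control replicate 2 (from 0.11 without control replicate 1 to 0.18 without eIF3m replicate 3). Rb1, Btg2 and Mdm2 did not pass with upper-quartile scaling, nor Cdkn2b, Rb1, Ephx1, Sesn1, Bbc3, Diablo, Birc2 and Ripk3 with DESeq2. Ripk3 did not pass with limma-voom or the 20 most abundant genes left out, nor Rb1 and Ripk3 with no filter. Mdm2 did not pass with the stricter filter, nor Cdkn2b and Birc2 with a replicate block. Ccnd1, Rb1 and Btg2 did not pass with no scaling factors, nor Cdk2, Cdkn2b, Rb1, Ephx1, Sesn1, Bbc3, Btg2 and Mdm2 with thinned libraries.

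TGF-beta and BMP genes counted 8 risen and 11 fallen of 26 (10 and 11 adjusted over the list alone; adjusted p = 0.480), with a median of 0.02, a mean of -0.09 and a test toward lower. Tgfb3 fell from 539 ± 6.73 to 194 ± 3.85 CPM (-1.47 ± 0.04 SE), and the co-receptor Eng by 0.74 on the log2 scale, while follistatin, Fst, rose (0.49 ± 0.05). Complement and coagulation genes counted 3 risen and 6 fallen of 14 (3 and 6 adjusted over the list alone), with a median of -0.18, a mean of 0.33 and a test toward lower (adjusted p = 0.0320, and adjusted p = 0.209 with an estimated correlation). The call was lost without eIF3m replicate 3 (adjusted p = 0.0517) and with no filter (0.0820), in a range of 3.04e-04 to 0.209. C1r, C1s, Clu and F3 fell by 0.60, 0.68, 0.34 and 0.36 on the log2 scale. Cfd (3.79 ± 0.73 SE), at or under 3 counts in each control library, C4b (3.12 ± 0.83) and Cfb (0.97 ± 0.34) rose, and without eIF3m replicate 1, the library with Hbb at 2133 CPM, C4b (0.35) and Cfb (0.51) did not pass; Cfb was also lost without control replicate 1 (0.76) or 2 (1.07). Genes of MHC class I presentation counted 3 risen, Psmb10 (0.35), Nlrc5 (0.55) and Psmb9 (0.68), and 5 fallen, Erap1 (-0.81), Tapbp (-0.55), Tap1 (-0.36), B2m (-0.25) and RT1-A1 (-0.51, of a family of near-identical genes), of 15 (3 and 6 adjusted over the list alone; adjusted p = 0.366). Their median was -0.10, turning to 0.04 with no scaling factors, their mean 0.0045 and the test toward lower. Nlrc5 was lost without control replicate 2 (0.57) or 3 (0.50) or eIF3m replicate 2 (0.50) or 3 (0.54), and Psmb9 without control replicate 2 (0.73) or 3 (0.51) or eIF3m replicate 1 (0.45) or 2 (0.64). Circadian clock genes counted 3 risen, Per2 (0.45), Per3 (0.78) and Ciart (0.74), and 2 fallen, Per1 (-0.44) and Bhlhe40 (-0.42), of 16 (3 and 2 adjusted over the list alone; adjusted p = 0.595). Glucocorticoid response genes counted 2 risen, Errfi1 (0.79) and Ddit4 (0.43, and 0.29 without eIF3m replicate 1), and 5 fallen, Angptl4 (-2.06), Sgk1 (-0.48), Per1, Dusp1 (-0.43) and the receptor Nr3c1 (-0.32), of 14 (2 and 5 adjusted over the list alone; adjusted p = 0.341), with a median of 0.01, a mean of -0.12 and a test toward lower. Adipocyte markers counted 2 risen, Cfd and Scd (0.37), and 3 fallen, Slc2a4 (-1.44), Dgat2 (-0.45) and Fasn (-0.13), of 9 (2 and 3 adjusted over the list alone; adjusted p = 0.595), with a median of -0.01, positive with upper-quartile scaling and no scaling factors, a mean of 0.20 and a test toward lower. Scd was lost without control replicate 2 (0.38) or 3 (0.33) or eIF3m replicate 3 (0.23), and Fasn without any library but eIF3m replicate 1 (from -0.14 without control replicate 1 to -0.09 without eIF3m replicate 3), turning to 0.01 with no scaling factors. Epicardial and mesothelial markers counted 1 risen, Tbx18 (0.46), and 2 fallen, Krt7 (-0.90) and Msln (-0.69), of 5 (1 and 2 adjusted over the list alone; adjusted p = 0.595), with a median of 0.06, a mean of -0.18 and a test toward lower, and of 3 tested Schwann and neural markers 0 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone; adjusted p = 0.697). Fasn did not pass with upper-quartile scaling or the stricter filter, nor C4b, Cfb, Nlrc5, Psmb9 and Scd with DESeq2. C4b did not pass with limma-voom or robust dispersion, nor Nlrc5 with no filter. Cfb did not pass with a replicate block, nor B2m with no scaling factors. Nlrc5, Psmb9, B2m and Scd did not pass with thinned libraries.

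Blood, vessel and leukocyte transcripts stood highest in eIF3m replicate 1 for 49 of 56 listed genes with a count, or 87.5%. RNA of another source in that library would give this, but the count restates the observation that prompted it and is no separate support. Y-linked genes, a list written after the data were seen, had 36 counts there and 0 in the other 5 libraries. A response to the siRNA would raise these transcripts in the other eIF3m libraries too, and their summed excess there was -1.19% of that of replicate 1 in replicate 3 and 1.92% in replicate 2. Most of that sum is erythroid, at 6256 CPM in eIF3m replicate 1 and 240 in replicate 2, against 35.2 to 80.8 in controls. Endothelial markers were at 300, 102 and 92.5 CPM in eIF3m replicates 1, 2 and 3 and 148 to 157 in controls. Leukocyte markers were at 82.5, 29.6 and 26.6 CPM there and 33.2 to 34.1 in controls. Whether eIF3m replicate 2 holds some of the same RNA was not tested. Eif3m stood at 91.5 CPM in eIF3m replicate 1, below all controls, against a control library under a wrong label. A candidate explanation is a small amount of RNA from tissue or cells with blood, which no label names; the step at which it could have entered was not tested.

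Of 32 contractile list members, 20 had a control mean below 5 CPM and 12 lay at or above it, among them Tnnt2 (366 CPM) and Tnnc1 (153); of the calcium-handling genes Atp2a2 stood at 763, Casq2 at 436 and Gja5 at 260 CPM. Ventricular myocytes as the source of most RNA were argued against by Myh6, Myh7, Nppa and Nppb, fixed as genes to report before the data were examined but picked for this test afterwards, whose highest level in any library was 2.21 CPM. Cardiac fibroblasts stay open, since 9 of 20 fixed markers, 7 of the 20 also in another list, had a control mean of at least 5 CPM, such as Col1a1 (12027 CPM), Vim (2420), Col3a1 (1926) and Ddr2 (615), and 11 did not, such as Dcn (1.08), Lum (0.655) and Pdgfra (0.455). Of 21 markers of skeletal myoblasts, listed after levels had been seen and 0 of them in a fixed list, 11 had a control mean of at least 5 CPM, among them Cdh15 (224 CPM), Rapsn (103), Musk (51.3), Chrnb1 (34.9) and Myog (19.3). A hypothesis is that cells of the skeletal muscle lineage may supply most of the RNA, but because the list followed the levels, the labels give embryonic heart muscle as the origin and these data hold no other sample of known identity, the source cannot be told apart.

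For the number of changed genes, the splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real grouping gave 4920 changed genes, 2220 higher, 2700 lower and 520 changed at least 2-fold, and the highest other split gave 1 changed gene, changed at least 2-fold, which counts for either direction because the direction of another split is arbitrary. The real grouping called 21 lists, and the other splits called 7 to 12. The real split was in each case the 1 of 10 with a result as large. Each other split mixes control and eIF3m libraries in both groups, so a real difference widens its spread and few genes can pass. The gene counts of those splits thus cannot support the real grouping. Their list counts come from the same mixed groups, which can hold part of the siRNA difference. The 7 to 12 lists are therefore no measure of false list calls, and the 21 lists gain no support from them. With all libraries thinned to the smallest, 3236 genes changed, against 4920 at full depth, and 3058 calls were shared in the same direction. For those shared calls this argued against a difference in library size. The limit set for that test was the highest count of the mixed splits, which few genes can pass, so meeting it adds nothing. Whether the libraries of a group are repeats of 1 culture cannot be told apart from separate cultures: the biological coefficient of variation was 4.02% among controls, 10.9% among eIF3m libraries and 5.70% without eIF3m replicate 1, with no reference for these cells.

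Single libraries stood apart for a few genes chosen after their values were seen. Eif5, an initiation factor, was at 1803 CPM in eIF3m replicate 2 and between 362 and 540 CPM in the other 5 libraries. Nupr1 was at 154 CPM in that library and between 4.56 and 6.40 CPM elsewhere. Rmrp, a non-coding RNA, was at 643 CPM in eIF3m replicate 1, 34.9 CPM in replicate 2 and between 5.40 and 9.71 CPM in the others.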
